A study of Saccharolobus islandicus REY15A with 9 samples.

How the data were processed

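Gene expression was measured by RNA sequencing in 9 libraries of Saccharolobus islandicus REY15A, 3 each from strains carrying the empty plasmid, an aCcr2 plasmid and an aCcr3 plasmid, all induced with arabinose. Per the labels' protocols, total RNA was made into libraries with an Illumina TruSeq RNA kit. The submitters' processing notes name HISAT2 2.0.5 as the aligner. The notes also name a mouse genome build and the extraction protocol names a mammalian tissue, and neither fits the organism or the coordinates in the table, which lie on the REY15A chromosome. The program that counted reads and its strand setting are not given in the sources used here, so reads of overlapping or antisense genes were not told apart. Genes with near-identical copies, such as transposases, may share reads.

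Per the file headers, the deposited table holds a raw read count per gene and library, and the values were whole numbers. The table also holds FPKM per gene and library that the authors deposited, each a count divided by the gene's length and by 1 constant per library that is not the total of the counts. Per the file headers, it further holds the authors' normalised count, log2 fold change, p-value and adjusted p for aCcr2 and for aCcr3 against the control, with a dash for genes without a value. The raw counts were used for all tests. The FPKM served for 1 alternative filter, and the authors' comparison was used for its numbers of genes. All columns per library were assigned to a sample by their names, leaving 0 unassigned.

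Of the 2805 genes in the table, 2780 were matched by locus tag to the reference gene table of the REY15A assembly, 2706 of them with the same start and end, and 2637 had an older SiRe tag. Gene symbols and products come from these tables. Total counts per library were 2940293, 2914535 and 2570205 in the control, 2615961, 2546941 and 2780343 with aCcr2, and 2971583, 3053590 and 2798623 with aCcr3. The 10 most abundant genes held between 20.4% and 24.0% of the counts. TMM factors ran from 1.08 to 1.09 in the control, from 0.928 to 0.946 with aCcr2 and from 0.986 to 0.993 with aCcr3.

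Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which kept 2551, and libraries were scaled with TMM. A quasi-likelihood model with 1 mean per group was fitted to the 9 libraries together, and aCcr2 against control, aCcr3 against control and aCcr2 against aCcr3 were tested as contrasts. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with calls at 0.05 and a second count of genes with an absolute log2 fold change of at least 1. Levels are CPM, counts scaled by the TMM library sizes. For genes with 3 counts or fewer in a group, the ratio of summed counts is given with an exact 95% interval. These intervals cover counting error only.

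Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 22 lists of a comparison. Camera with an estimated correlation and fry were run beside it. The 22 lists are cell division, DNA replication, chromosome organisation and segregation, nucleotide biosynthesis, DNA repair and recombination, ribbon-helix-helix regulators, other transcription regulators, and RNA polymerase with basal transcription factors. The others are ribosomal proteins, translation factors and tRNA synthetases, archaellum and pili, S-layer and protein glycosylation, CRISPR-Cas, toxin-antitoxin, proteasome with chaperones and heat shock, terminal oxidases and respiratory chain, ATP synthase, TCA cycle and central carbon, amino acid biosynthesis, sugar uptake and arabinose use, transposases and mobile elements, and membrane lipid and isoprenoid synthesis. Members were taken by locus tags and by words in the gene name or product. After the table was seen, 32 matches that rested on spelling alone, such as flap endonucleases in the archaellum list, were left out by their product names.

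The groups, tests, lists, rule for named genes and all but 3 of the alternatives were set before the data were examined. Per comparison with the control, the rule names the 10 largest rises and the 10 largest falls among called genes whose 3 libraries all lie on one side of the 3 control libraries. It adds every cell division gene and aCcr1, and up to 4 called members with the largest absolute fold change from each list that was called or holds at least 3 called genes. Between the strains it names the 5 largest differences each way. The rule names 105 genes in each comparison with the control, of which the text gives a part, and 10 between the strains. Rgy between the strains and dps with aCcr3 are quoted because the rule named them in another comparison.

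The procedure was tested on simulated data drawn from the real means and library sizes, with 200 genes changed by known amounts. In the simulated aCcr2 comparison (2511 genes), 52% of genes changed 1.25-fold, 84% of those changed 1.5-fold, 98.0% of those changed 2-fold and 98% of those changed 4-fold were called. For aCcr3 (2517 genes) the shares were 38%, 88%, 94% and 100%, and between the strains (2508 genes) 36%, 87.8%, 96% and 100%. Unchanged genes made up 1.79%, 4.79% and 3.05% of the calls. Far fewer genes were changed here than were called in the real comparisons, so these shares may differ there. A changed list of 25 genes was called in each, and 0 of 20 unchanged lists. Genes were drawn independently of each other, so this does not test camera on lists of correlated genes. Unchanged groups against the same controls were simulated 50 times for the overlap of the comparisons.

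In 18 alternatives for the gene counts, 1 choice was changed at a time, except that quantile normalisation was run with limma-voom and DESeq2 with its own size factors, so that scaling and test both changed in these. They were no filter on low counts, a mean of at least 10 FPKM, median-of-ratios scaling, quantile normalisation with limma-voom, total-count scaling, DESeq2 1.42.0, the replicate number as a block, fits of only the groups compared, each of the 9 libraries left out, and tRNA and mobile element genes left out. For the lists, one alternative kept the 32 matches by spelling. Chromosome stretches of 100 kb were tested against 10000 shuffles of blocks of 10 neighbouring genes with numpy 2.4.6 and Python 3.11.15, and figures were drawn with matplotlib 3.10.9.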

Results

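RNA was sequenced from the thermoacidophilic archaeon Saccharolobus islandicus REY15A carrying 1 of 3 plasmids. One strain overexpressed the transcription factor aCcr2, one overexpressed aCcr3, and the control carried the empty plasmid pSeSD, with arabinose as the inducer in all 3 groups. Each group had 3 libraries, giving 9 in total. Per the labels, cultures were started at an OD600 of 0.05 and collected after 12 h at an OD600 of about 0.2. Total counts over genes ranged from 2546941 in aCcr2 replicate 2 to 3053590 in aCcr3 replicate 2. The labels do not state whether the 3 libraries of a group came from separate cultures, so the p-values below may measure technical spread only. Of the 2805 genes in the table, 2551 had enough reads to be tested. A gene is said to have risen or fallen where edgeR's quasi-likelihood test called it at a Benjamini-Hochberg adjusted p of 0.05, and fold changes are on the log2 scale with their standard errors.

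The libraries separated by strain. Across the tested genes, Pearson's r of log2 CPM lay between 0.991 and 0.994 within groups. It lay between 0.961 and 0.964 for control against aCcr3, between 0.918 and 0.923 for aCcr2 against aCcr3, and between 0.872 and 0.879 for control against aCcr2. These correlations are across genes, which are not independent replicates. The first principal component held 75.2% of the variance and set the aCcr2 libraries (31.4 to 32.0) apart from the other 6. On it the aCcr3 libraries (-8.5 to -8.0) lay between aCcr2 and control (-24.1 to -22.8). The second held 15.8% and also parted control from aCcr3. Within both overexpression groups replicate 1 lay further from the other libraries, measured as chi-square per degree of freedom of the counts of a pair (genes with at least 20 counts in the pair), where counting error alone gives about 1. With aCcr2 it was 7.76 and 6.17 for replicate 1 against 2 and 3, and 2.69 for 2 against 3. With aCcr3 it was 9.60 and 8.46, and 2.89, and control pairs ranged from 2.22 to 3.83. Without aCcr2 replicate 1, edgeR called 1926 genes with aCcr2 and 1712 between the strains, against 1963 and 1756 with all libraries. Without aCcr3 replicate 1 it called 1434 with aCcr3 and 1730 between the strains, against 1451 and 1756.

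The comparison of the aCcr2 strain with the empty plasmid asks which transcripts change when this factor is overproduced, in a study whose title concerns transcriptional repression during the cell cycle. With aCcr2, the transcript of dps, a ferritin-like protein that binds and protects DNA (SIRE_RS02340, chromosome positions 418965 to 419546), rose from 58.9 ± 3.18 to 8249 ± 170 CPM (counts normalised to library size, mean ± SD, n = 3), a log2 fold change of 7.13 ± 0.08. All 6 measured cell division genes fell, and so did aCcr1 (SiRe_0197), a cell cycle regulator of the ribbon-helix-helix family, which went from 242 ± 9.36 to 16.0 ± 1.41 CPM (n = 3), a change of -3.91 ± 0.11. In total 1963 genes changed, 986 up and 977 down, and 412 of the rises and 385 of the falls were at least 1 on the log2 scale. With library sizes taken as plain total counts the split was 766 up and 1222 down. That scaling moved the median log2 fold change of all genes from -0.018 to -0.23, so directions here are relative to the TMM scale.

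The cell division list holds the ESCRT-related Cdv proteins, which form the constriction machinery of this archaeon. It was the 1 list of 22 that camera called with aCcr2 (adjusted p = 0.0097, median log2 fold change -1.13), and 6 of 6 members fell. The camera adjusted p was 0.248 with an estimated correlation in place of the preset one. That estimate was -0.16, below the preset 0.01, so correlated members do not account for the higher p. Its cause was not tested. SiRe_1550 (cdvB1/B2, positions 1442392 to 1443153) showed the largest change of the 6 at -2.35 ± 0.06, from 8053 ± 131 to 1581 ± 82.4 CPM (n = 3). SiRe_1200 (cdvB1/B2, positions 1150853 to 1151518) changed by -1.40 ± 0.07. In the cdvA-cdvB-cdvC cluster, which starts at position 1125944 and ends at 1128673, the changes were -1.26 ± 0.07, -0.76 ± 0.08 and -0.998 ± 0.07. The change of cdvB3 was -0.55 ± 0.09. SiRe_1550 and SiRe_1200 carry the same gene name, and SiRe_1550 overlaps its neighbour by 47 bases, so reads may have been divided between such genes.

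**Figure D1:**
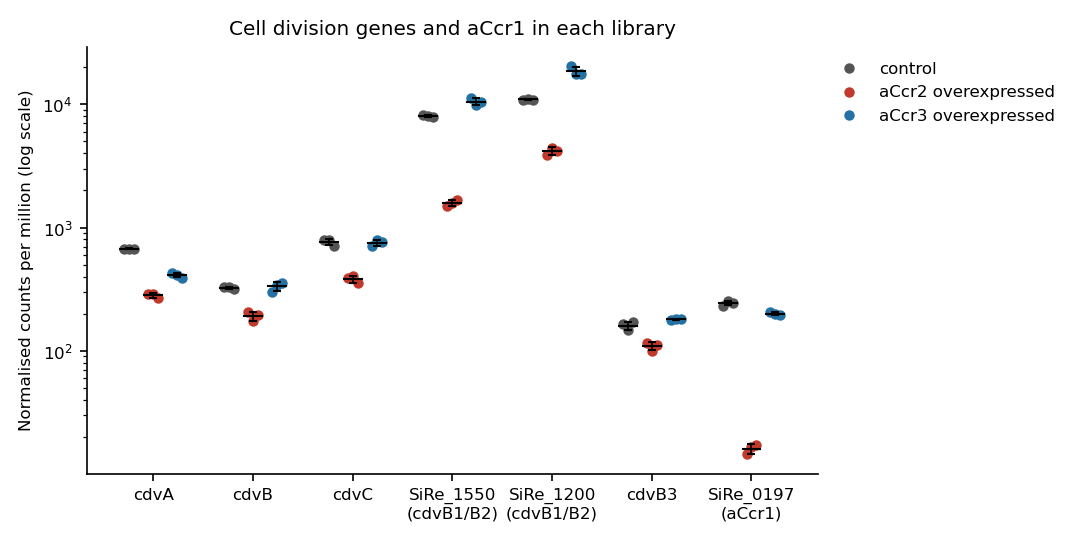
Normalised CPM (log scale) of the 6 cell division genes and aCcr1 in each of the 9 libraries, with 1 point per library and bars for the mean and SD of 3 libraries. In the aCcr2 strain all 7 genes lie below the control, while in the aCcr3 strain SiRe_1200 rose, SiRe_1550 rose (0.39, but -0.033 under quantile normalisation with limma-voom), and cdvA and aCcr1 fell.

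Of the 10 largest rises with aCcr2, 6 lay beside dps or polB2 or were these genes, and 4 lay elsewhere. Directly downstream of dps, the gene for a Rieske iron-sulfur protein (SIRE_RS02345) rose by 6.32 ± 0.17, and an AAA family ATPase gene upstream of it (SIRE_RS02330) by 4.05 ± 0.09. The gene matched to DNA polymerase 2 (polB2, SIRE_RS03135, positions 594585 to 596252) rose from 41.2 ± 0.835 to 1242 ± 28.0 CPM (n = 3), a change of 4.91 ± 0.09. Its neighbours SIRE_RS03130 and SIRE_RS03140, which share bases with it, rose by 4.84 ± 0.14 and 4.35 ± 0.16. The other large rises were a PaREP1 family gene (SIRE_RS14940, 4.40 ± 0.12), a gene of unknown function (SIRE_RS04585, 4.08 ± 0.09) and a gene for an ATP-binding protein (SIRE_RS01635, 3.72 ± 0.18). A TnpB-family gene (SIRE_RS03715) rested on few reads, 49 counts in the aCcr2 libraries against 2 in the control (both in replicate 3, so 0 without it), a ratio of 30.1 with an exact 95% interval of 7.91 to 256.

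Besides aCcr1, the largest falls with aCcr2 included a gene of unknown function (SIRE_RS10015, -4.85 ± 0.24), csa3, a CRISPR-associated regulator (-4.37 ± 0.54), and a rusticyanin-like copper protein (SIRE_RS03185, -3.12 ± 0.10). The value of csa3 rested on 0, 2 and 2 counts in the aCcr2 libraries, against 52, 29 and 29 in the control. Further genes of unknown function that fell were SIRE_RS00390 (-3.65 ± 0.15), SIRE_RS03180 (-3.35 ± 0.14) and SIRE_RS14710 (-3.26 ± 0.17). A putative integrase gene (SIRE_RS14055) and tRNA-Asp (SIRE_RS09055) changed by -3.23 ± 0.57 and -2.98 ± 0.42. The former rested on counts of 1, 1 and 3 in the aCcr2 libraries, and its change was -3.88 without aCcr2 replicate 3. For tRNA-Met (SIRE_RS09050) there was 1 count in the aCcr2 libraries (in replicate 2, so 0 without it) against 43 in the control, a ratio of 34.9 in favour of the control with an exact 95% interval of 5.95 to 1412. These intervals cover counting error only. All tRNA genes together held 0.066% to 0.072% of the counts in the control libraries and 0.034% to 0.040% with aCcr2. With aCcr3 the share was 0.042% to 0.045%. The class as a whole was thus thinly covered and lower in both overexpression strains than in the control.

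The counts per list below are to be read against all tested genes, of which 77.0% changed with aCcr2. Among genes of DNA metabolism, 9 of 20 measured replication genes rose with aCcr2 and 7 fell. DNA polymerase I (SIRE_RS07370) rose by 2.87 ± 0.07 and the Orc1-2 gene (SIRE_RS06235), of the initiator family, by 2.62 ± 0.10, whereas DNA polymerase 3 (SIRE_RS09745) changed by -1.10 ± 0.08. Of 23 repair and recombination genes, 10 rose and 7 fell. The neighbouring genes nurA (2.11 ± 0.10), mre11 (1.85 ± 0.08) and herA (1.51 ± 0.09), whose products process DNA double-strand ends, all rose. Of 15 genes of chromosome organisation and segregation, 5 rose and 9 fell, among the latter creN7 (-2.28 ± 0.10), a chromatin protein, and a ParA family gene (SIRE_RS01335, -2.86 ± 0.09). Of 24 nucleotide biosynthesis genes, 8 rose and 9 fell. Here pyrE, of pyrimidine synthesis, rose by 3.45 ± 0.10. Its neighbour pyrF had 0 counts in the control and 2 with aCcr2, so pyrE may not stand for this pathway. The genes thyX and dcd, both of thymidylate supply, changed by -1.02 ± 0.08 and -1.38 ± 0.08.

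Among regulators and the transcription machinery, 3 of 9 ribbon-helix-helix genes rose with aCcr2 and 6 fell. SIRE_RS15120 rose by 2.95 ± 0.08 and SIRE_RS08000 changed by -1.83 ± 0.10. Of 76 other transcription regulators, 22 rose and 41 fell, for example a metal-dependent regulator (SIRE_RS06830, 2.54 ± 0.08) and a helix-turn-helix gene (SIRE_RS10570, -2.44 ± 0.11). Of 23 genes for RNA polymerase and basal factors, 7 rose and 7 fell, with tfe at -1.33 ± 0.12. Of 65 ribosomal protein genes, 32 rose and 13 fell, with L13e (SIRE_RS01170) at 3.08 ± 0.12 and S7 (SIRE_RS09030) at -1.11 ± 0.06. Of 34 genes for translation factors and tRNA synthetases, 16 rose and 14 fell. Of 16 proteasome and chaperone genes, 9 rose and 3 fell, with the thermosome subunit gene thsA at 1.57 ± 0.06 and the proteasome-activating nucleotidase (SIRE_RS08775) at -1.57 ± 0.08.

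Metabolic lists moved in both directions with aCcr2. Of 43 amino acid biosynthesis genes, 22 rose and 10 fell, among the former both subunits of 3-isopropylmalate dehydratase (SIRE_RS01310, 2.86 ± 0.09, and SIRE_RS01305, 2.41 ± 0.07) and ilvD (1.93 ± 0.07), all of branched-chain amino acid synthesis. Of 28 genes of the TCA cycle and central carbon, 15 rose and 3 fell, with isocitrate lyase (aceA) at 2.20 ± 0.06 and phosphoenolpyruvate carboxykinase (SIRE_RS02025) at -2.15 ± 0.07. Of 11 sugar uptake and arabinose genes, 8 rose and 2 fell, and the glucose-binding protein gene glcS changed by 1.64 ± 0.05. Of 34 genes for terminal oxidases and the respiratory chain, 12 rose and 13 fell. Of 8 ATP synthase genes, 5 rose and 2 fell. Of 18 membrane lipid genes, 5 rose and 9 fell, with mevalonate kinase (mvk) at 1.25 ± 0.10.

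For the surface, defence and mobile element lists with aCcr2, 8 of 31 S-layer and glycosylation genes rose and 10 fell, and 2 of 7 archaellum and pili genes rose and 3 fell. Of 31 CRISPR-Cas genes, 8 rose and 15 fell, with crn1 at 1.97 ± 0.09 and cbp1 at -1.91 ± 0.19. Of 54 toxin-antitoxin genes, 28 rose and 15 fell, with the overlapping pair SIRE_RS01660 and SIRE_RS01655 at 2.85 ± 0.13 and 2.72 ± 0.17. Of 38 transposase and mobile element genes, 17 rose and 13 fell, and reads of near-identical copies make these values uncertain. Camera did not call any of the 21 lists other than cell division (adjusted p from 0.206 to 0.863). Over the 22 lists 468 members were called, and 467 when adjusted over the list alone. Median, mean and camera's direction differed in sign for archaellum, DNA repair, nucleotide biosynthesis and the respiratory chain. The medians of the lists archaellum, DNA replication, translation factors and transposases changed sign under total-count scaling.

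The comparison of the aCcr3 strain with the empty plasmid asks the same question of the other factor. With aCcr3, the cell division genes did not move together. SiRe_1200 rose by 0.76 ± 0.06, from 10971 ± 71.4 to 18527 ± 1583 CPM (n = 3), and SiRe_1550 rose by 0.39 ± 0.06, a value that turned to -0.033 under quantile normalisation with limma-voom. By contrast cdvA changed by -0.71 ± 0.06. The other members, cdvB (0.043 ± 0.08, and -0.088 under total-count scaling), cdvC (-0.026 ± 0.07) and cdvB3 (0.17 ± 0.08), did not pass the test (edgeR adjusted p = 0.65, 0.76 and 0.087). The change of aCcr1 was -0.28 ± 0.08. In total 1451 genes changed, 754 up and 697 down, with 138 rises and 98 falls of at least 1 on the log2 scale. The changed genes were 56.9% of those tested, and the counts per list below are to be read against that share. Under total-count scaling the split was 575 up and 971 down, and the median of all genes moved from -0.0072 to -0.14.

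The largest rises with aCcr3 were a sodium-solute symporter gene (SIRE_RS01775), which went from 22.4 ± 1.01 to 151 ± 19.1 CPM (n = 3), a change of 2.74 ± 0.13, and a radical SAM protein gene (SIRE_RS07740, 2.64 ± 0.07). Genes of unknown function followed, SIRE_RS02795 with 2.63 ± 0.20, SIRE_RS00630 with 2.37 ± 0.22, SIRE_RS04585 with 2.36 ± 0.10, SIRE_RS14770 with 2.15 ± 0.12 and SIRE_RS10200 with 1.95 ± 0.07. An IS110 transposase gene (SIRE_RS04325) rose by 2.41 ± 0.15, an OB-fold protein gene (SIRE_RS03635) by 1.91 ± 0.15 and polB2 by 1.84 ± 0.10. The largest falls were headed by csa3 (-2.60 ± 0.39), on 7, 5 and 5 counts in the aCcr3 libraries. Other large falls were a DUF871 family gene (SIRE_RS14260, -2.16 ± 0.16), a thiolase domain gene (SIRE_RS13030, -2.02 ± 0.09) and SIRE_RS10015 (from 75.3 ± 1.46 to 18.7 ± 3.51 CPM, n = 3). Also among them were SIRE_RS14710 (-1.99 ± 0.14), the semialdehyde dehydrogenase gene asd (-1.99 ± 0.11), SIRE_RS00090 (-1.90 ± 0.10) and an IS5 family transposase gene (SIRE_RS14500, -1.88 ± 0.33). Both permease genes of a sugar transporter, SIRE_RS05505 and SIRE_RS05510, changed by -1.91 ± 0.17 and -1.87 ± 0.18.

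The list of the TCA cycle and central carbon was the 1 list that camera called with aCcr3 (adjusted p = 0.0012, median log2 fold change 0.43), with 20 of 28 members up and 5 down. Its adjusted p in camera was 0.605 with an estimated correlation. Examples were isocitrate lyase (aceA, 1.55 ± 0.06), a phosphoglycerate mutase (SIRE_RS00255, 1.82 ± 0.14) and the glyceraldehyde dehydrogenase subunits cutC (1.25 ± 0.09) and cutB (1.25 ± 0.07). Of 43 amino acid biosynthesis genes, 9 rose and 17 fell, with SIRE_RS01310 at 1.16 ± 0.09 and lysX at -0.73 ± 0.06. Of 11 sugar uptake and arabinose genes, 4 rose and 6 fell, and araD, an arabinonate dehydratase, changed by 1.26 ± 0.13. Of 34 respiratory chain genes, 11 rose and 6 fell, of 8 ATP synthase genes 2 rose and 2 fell, and of 18 membrane lipid genes 7 rose and 8 fell, with hmgA at 0.75 ± 0.08.

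In DNA metabolism, 5 of 20 replication genes rose with aCcr3 and 2 fell, with DNA polymerase I (SIRE_RS07370) at 0.42 ± 0.07. Of 23 repair and recombination genes, 9 rose and 2 fell, among them the Holliday junction resolvase gene hjc (1.78 ± 0.11) and a tyrosine recombinase gene matched to XerA (SIRE_RS08260, 1.44 ± 0.06). Of 15 genes of chromosome organisation, 5 rose and 6 fell, and rgy, reverse gyrase, which introduces positive supercoils, rose by 1.43 ± 0.07. Of 24 nucleotide biosynthesis genes, 5 rose and 4 fell, with pyrE at 1.20 ± 0.11, although its neighbour pyrF had 0 counts. Among regulators, 4 of 9 ribbon-helix-helix genes rose and 3 fell, and 17 of 76 other regulators rose and 34 fell, with arnR, an activator of archaellum genes, at 1.14 ± 0.09. Of 23 genes for RNA polymerase and basal factors, 2 rose and 7 fell.

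Of 65 ribosomal protein genes, 13 rose and 15 fell with aCcr3, of 34 translation genes 9 rose and 7 fell, and of 16 proteasome and chaperone genes 9 rose and 2 fell, with Hsp20 (SIRE_RS01090) at 0.85 ± 0.06 and Hsp14 (SIRE_RS13135) at 0.79 ± 0.07. For 31 CRISPR-Cas genes the counts were 12 up and 4 down, for 54 toxin-antitoxin genes 22 up and 11 down, and for 31 S-layer and glycosylation genes 10 up and 9 down. The toxin-antitoxin pair SIRE_RS02990 and SIRE_RS02995 rose by 1.77 ± 0.09 and 1.74 ± 0.13. Of 7 archaellum and pili genes 3 rose and 2 fell, and of 38 transposase genes 5 rose and 8 fell. Of the 6 cell division genes 2 rose and 1 fell, and the list median of 0.11 changed sign under quantile normalisation with limma-voom and under total-count scaling. Camera did not call any of the 21 other lists (adjusted p from 0.167 to 0.984). Over all lists 346 members were called, and 344 when adjusted over the list alone. Median, mean and camera's direction differed in sign for chromosome organisation, membrane lipids, ribbon-helix-helix regulators and the S-layer list. Under total-count scaling the medians of ATP synthase, DNA repair, DNA replication, nucleotide biosynthesis, S-layer, respiratory chain and translation also changed sign, and those of nucleotide biosynthesis and S-layer did so under quantile normalisation with limma-voom too.

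**Figure D2:**
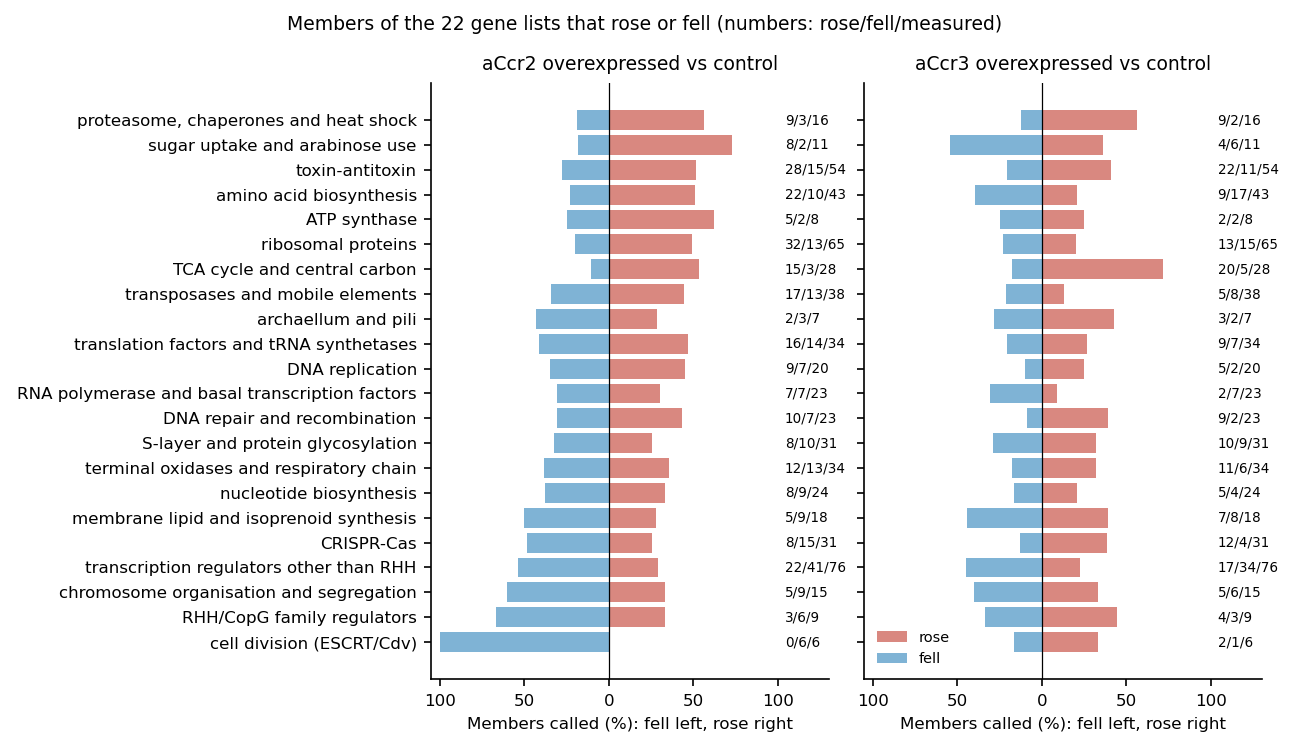
Share of the measured members of each of the 22 gene lists, in percent, that rose (right) or fell (left) with aCcr2 and with aCcr3 against the control, with the numbers risen, fallen and measured beside each bar. All 6 cell division genes fell with aCcr2, and 20 of 28 genes of the TCA cycle and central carbon rose with aCcr3; under total-count scaling fewer genes rose in both comparisons.

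The direct comparison of both overexpression strains tests where the effects of aCcr2 and aCcr3 differ. The transcripts further above aCcr3 in the aCcr2 strain were headed by the Rieske gene (SIRE_RS02345, 6.07 ± 0.17), dps (5.99 ± 0.07) and an MFS transporter gene (SIRE_RS11020, 4.16 ± 0.07). A transposase gene (SIRE_RS02055, 4.13 ± 0.59) and SIRE_RS14680 (4.12 ± 0.42) rested on few reads in the aCcr3 libraries, and the former value was 5.34 without aCcr3 replicate 1. Lower with aCcr2 than with aCcr3 were aCcr1 (-3.64 ± 0.11) and the genes of unknown function SIRE_RS13180 (-3.55 ± 0.08) and SIRE_RS07980 (-3.38 ± 0.07). Rgy differed by -3.18 ± 0.07. For tRNA-Met (SIRE_RS09050) the counts were 1 (0 without aCcr2 replicate 2) and 23, a ratio of 19.5 in favour of aCcr3 with an exact 95% interval of 3.17 to 805. In total 1756 genes differed (68.8% of those tested), 887 higher and 869 lower with aCcr2. Of these, 254 and 248 differed by at least 1 on the log2 scale. Under total-count scaling the split was 767 higher and 1001 lower, with 223 and 274 by at least 1.

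Camera called 4 lists between the strains. Cell division was lower with aCcr2 (adjusted p = 0.0007, median log2 difference -0.89), with 6 of 6 genes lower, and its camera adjusted p was 0.141 with an estimated correlation. Amino acid biosynthesis was higher with aCcr2 (adjusted p = 0.0003, median 0.46), with 31 genes higher and 1 lower of 43, and 0.162 was its camera adjusted p with an estimated correlation. Ribosomal proteins were higher (adjusted p = 0.0136, median 0.25), with 37 higher and 6 lower of 65. This camera call had an adjusted p of 0.299 with an estimated correlation, and of 0.215 when the genes were ranked by DESeq2. Sugar uptake and arabinose use was higher at an adjusted p of 0.0485 in camera (median 0.81), with 8 higher and 2 lower of 11. Its adjusted p was 0.299 with an estimated correlation, and leaving out control replicate 3, aCcr2 replicate 3, aCcr3 replicate 1 or aCcr3 replicate 2 ended the call (camera adjusted p = 0.0525, 0.0567, 0.0728 and 0.0508). The other 18 lists were not called by camera (adjusted p from 0.151 to 0.682). In these lists 425 members were called, the same number as when adjusted over the list alone. Median, mean and camera's direction differed in sign for DNA replication, nucleotide biosynthesis, the respiratory chain and the other transcription regulators, and another scaling turned the medians of DNA replication and of these regulators.

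With an estimated correlation, camera called 0 lists in each comparison, and 1, 0 and 2 lists had an unadjusted p under 0.05 with aCcr2, with aCcr3 and between the strains. Fry, which asks whether the genes of a list move one way on balance, called 18, 14 and 17 of the 22 lists. Its test for change in either direction called 22 in each. Neither fry test compares a list with the other genes. As 77.0%, 56.9% and 68.8% of all tested genes were called, almost any list could pass. No conclusion about single lists is drawn from the fry counts. Groups of libraries did not overlap for 2009 genes with aCcr2 (78.8%), 1611 with aCcr3 (63.2%) and 1781 between the strains (69.8%), where chance gives 10%.

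Many genes changed with both factors. Against the control, 1236 genes changed in both strains, 551 of them up in both and 527 down in both. A further 55 rose with aCcr2 and fell with aCcr3, and 103 did the reverse. Under total-count scaling 383 genes were up in both and 765 down in both. Independent lists of these sizes would share 291 rises and 267 falls (173 and 465 under total-count scaling). Pearson's r of the fold changes across genes was 0.61, and 0.475 on average (0.428 to 0.517) in 50 simulated pairs of unchanged groups against the same controls, in which 0 genes were called in both. The covariance was 0.411, against 0.00974 in the simulated groups, a difference of 0.401. This difference argues against spread between the 3 control libraries as the main source of the covariance. A deviation common to all 3 control libraries was not simulated, and they were too few to be divided between the comparisons. Part of the excess in shared calls may therefore still come from the shared controls. Fold changes had the same sign for 74.1% of genes, against 66.1% in the simulations. The simulated r and share of the same sign come from groups without changed genes, where only the shared controls link the fold changes.

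Of the 2178 genes that changed in either strain, 1687 (77.5%) differed between aCcr2 and aCcr3 by the direct test, and the fold change was the larger with aCcr2 for 1392. Of the 727 genes called with aCcr2 alone, 637 differed between the strains. Of the 215 called with aCcr3 alone, 149 differed. Shared rises included polB2 (4.91 with aCcr2, 1.84 with aCcr3) and dps (7.13 and 1.13). The csa3 gene fell in both (-4.37 and -2.60), on few reads in either overexpression strain.

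**Figure D3:**
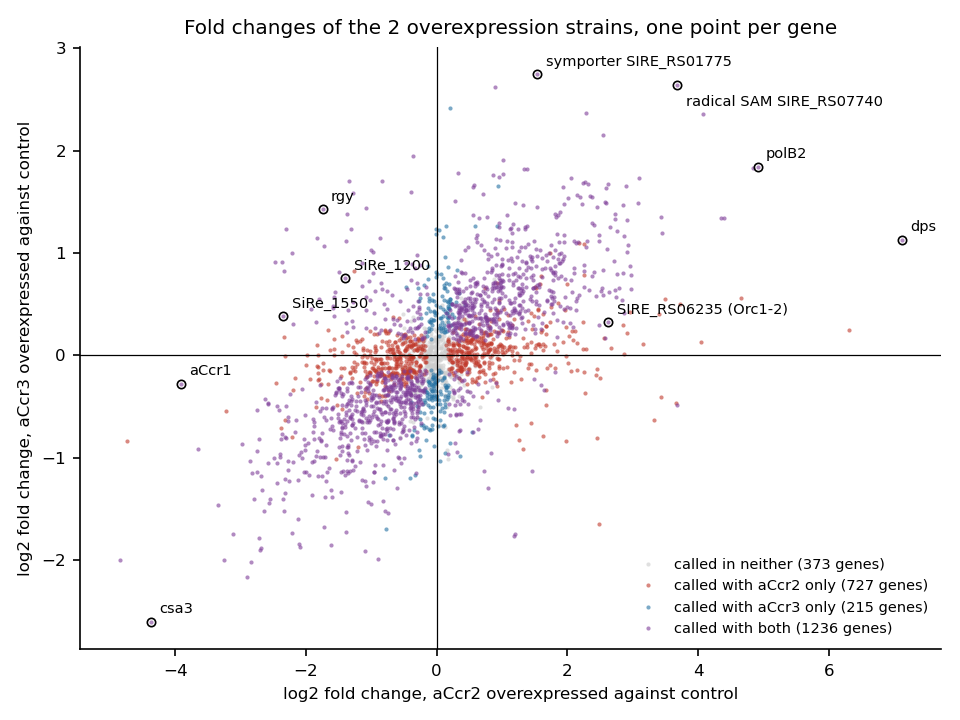
Log2 fold changes against the control with aCcr3 (vertical axis) and with aCcr2 (horizontal axis), 1 point for each of the 2551 tested genes, coloured by the comparisons in which the gene was called. The 1236 genes called in both lie mostly in the lower left and upper right, and rgy, SiRe_1200 and SiRe_1550 are among those with opposite signs (SiRe_1550 with aCcr3 was -0.033 under quantile normalisation with limma-voom).

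In the table of differential expression that the authors deposited, 1913 genes had an adjusted p below 0.05 for aCcr2 against control, 973 of them higher and 940 lower. For aCcr3 the numbers were 1351, 712 and 639. The loci of the plasmid-borne aCcr2 and aCcr3 genes were not analysed here and the extent of overexpression was not compared.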

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

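The difference between the strains was a planned test, while the limit of 1 on the log2 scale in both strains was chosen after the data were seen. Of all tested genes, 15 changed in opposite directions in the 2 strains by at least that limit, and differed between them by the direct edgeR test, and the 5 of them that the rule for named genes picked in any comparison are given here. A gene of unknown function (SIRE_RS13180) changed by -2.31 ± 0.07 with aCcr2 and 1.24 ± 0.07 with aCcr3, a difference of -3.55 ± 0.08. Rgy (SIRE_RS05690), reverse gyrase, changed by -1.75 ± 0.07 with aCcr2 and by 1.43 ± 0.07 with aCcr3, a difference of -3.18 ± 0.07. A ParA family gene (SIRE_RS10010) changed by -1.72 ± 0.16 with aCcr2 and 1.07 ± 0.12 with aCcr3, a difference of -2.79 ± 0.14. A tyrosine recombinase gene (SIRE_RS08260) changed by -1.07 ± 0.07 with aCcr2 and 1.44 ± 0.06 with aCcr3, a difference of -2.51 ± 0.07. An IS256 transposase gene (SIRE_RS02060) went the other way, 1.20 ± 0.08 with aCcr2 and -1.74 ± 0.10 with aCcr3, a difference of 2.94 ± 0.10, and reads of further copies of this element were not told apart from it.

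Lists whose medians had opposite signs in the 2 strains and which camera called between them were also singled out. Cell division differed by a median of -0.89 (-1.13 with aCcr2, 0.11 with aCcr3), and the latter median turned under quantile normalisation with limma-voom and under total-count scaling. Amino acid biosynthesis differed by 0.46 (0.30 with aCcr2, -0.18 with aCcr3) and ribosomal proteins by 0.25 (0.22 with aCcr2, -0.029 with aCcr3). Sugar uptake and arabinose use differed by 0.81 (0.34 with aCcr2, -0.34 with aCcr3). With an estimated correlation the camera adjusted p of these 4 lists was 0.141, 0.162, 0.299 and 0.299. No explanation was tested for these genes and lists.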

How the results depend on the processing

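Total-count scaling, the fit without tRNA and mobile element genes, and the lists with all matches by spelling were chosen after seeing the data, and the other alternatives were planned. The table holds counts, so the pseudocounts and the limma setting planned for FPKM alone were not run. Every count of changed genes stayed within 1.5 times its value in each alternative. Changed genes ranged from 1896 to 2007 with aCcr2, from 1312 to 1546 with aCcr3 and from 1652 to 1773 between the strains. With 1 library left out the ranges were 1896 to 2007, 1312 to 1499 and 1652 to 1736, and DESeq2 called 1901, 1374 and 1673 genes. The replicate block gave 1915, 1372 and 1681 calls. Libraries with the same number did not deviate together, with correlations of their deviations from -0.295 to 0.0165 over 9 pairs, and each library correlated best with one of another number, so the number was not treated as pairing. Among the named genes and the lists, the block ended the call of the sugar uptake list alone. Of 220 named results, 210 kept their side of the threshold in all alternatives that gave them a value, and 209 kept their direction as well. Of the called ones, direction turned for SiRe_1550 (SIRE_RS07855) with aCcr3, 0.39 with TMM in edgeR and -0.033 under quantile normalisation with limma-voom (limma adjusted p = 0.591), where scaling and test both differ, and the cause was not tested. With aCcr3 it also turned for cdvB and cdvC, which edgeR did not call with TMM and all libraries: cdvB to -0.088 under total-count scaling and -0.00055 without aCcr3 replicate 3, and cdvC to 0.0029 without control replicate 2 and 0.018 without aCcr3 replicate 1. In 17 cases of 3934 a named gene lost its call at the same direction, 16 of them with aCcr3. With aCcr2 this was the CDP-archaeol synthase gene SIRE_RS06205 without aCcr2 replicate 2 (edgeR adjusted p = 0.0534). In 1 case a gene gained a call, cdvC with aCcr3 under total-count scaling (-0.16, edgeR adjusted p = 0.0497).

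The sugar uptake list between the strains lost its camera call in 8 of 18 alternatives, at adjusted p of 0.0889 with no filter, 0.0508 with at least 10 FPKM, 0.0516 with the block, 0.0581 with only the groups compared and 0.0508 to 0.0728 with a library left out. DESeq2 ended the call of ribosomal proteins (camera adjusted p = 0.215) and added chromosome organisation (0.0263). The cause of these changes was not tested. At these depths a gene changed 1.25-fold was called in 36% to 52% of simulated cases.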

Other observations

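The test of scaling for the dps and polB2 genes and that of the pyrF reads were chosen after the results were seen, and the genes named here beyond those above were picked after their values were seen. Around dps, the zinc ribbon gene SIRE_RS13715 (3.44 ± 0.19) and the metal cation transporter gene SIRE_RS02335 (2.97 ± 0.13) also rose with aCcr2, so that 6 neighbouring genes from position 415903 to 420478 went up together. The next gene, SIRE_RS02355, changed by -0.84 ± 0.20. With aCcr3, dps (1.13 ± 0.08), SIRE_RS02335 (0.64 ± 0.15) and crn1 (0.57 ± 0.10) of these 6 rose, while the Rieske gene (0.24 ± 0.35), SIRE_RS02330 (0.13 ± 0.11) and SIRE_RS13715 (-0.41 ± 0.30) did not pass the test (edgeR adjusted p = 0.572, 0.345 and 0.25). The genes that flank the polB2 cluster, SIRE_RS03125 and SIRE_RS03150, rose with aCcr2 by 1.74 ± 0.52 and 1.40 ± 0.39, less than the polB2 genes.

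The first pattern weighed is the rise of dps, the polB2 genes and orc1-2 with aCcr2, which are known to be induced by DNA damage in this genus. A few abundant genes that shift the scale would raise these 5 genes only by as much as all others. Other scalings moved the median of all genes by at most 0.21 and left the 5 at 2.41 or more. The 5 were picked after their large rises were seen, so this outcome was all but fixed in advance. It shows only that these rises hold under each scaling tried. A DNA damage response predicts that other genes of it rise, and the median of 6 such genes was 1.49. Of these tfb3 (SiRe_1717, 1.52 ± 0.14), cedA1 (SiRe_1316, 2.43 ± 0.08) and cedA (SiRe_1317, 1.84 ± 0.06) rose, while of 3 ups pilus genes SiRe_1881 rose (1.47 ± 0.07) and SiRe_1878 (-0.29 ± 0.09) and SiRe_1879 (-0.56 ± 0.10) fell, as did their neighbour SIRE_RS09570 (-0.79 ± 0.13), which is not among the 6. A DNA damage response may therefore be part of this pattern as a hypothesis, and a direct effect of aCcr2 on these genes stays open and untested.

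The second pattern is that fold changes with aCcr2 differed between 26 stretches of the chromosome of 100 kb, with an SD of their medians of 0.380 against 0.195 in shuffled blocks of neighbouring genes (permutation p = 0.0009). On the TMM scale 6 had a median of at least 0.3 (at 200 to 600, 700 to 800 and 2000 to 2100 kb, 491 genes, medians from 0.35 to 0.93) and 4 had one of -0.3 or less (at 1600 to 1700 and 1900 to 2000 kb and from 2400 kb to the end, the lowest -0.61). Control levels in the 6 raised stretches were lower (median 43.5 against 138 CPM), but with the dependence on level removed the spread remained larger than shuffled (SD 0.302 against 0.184, permutation p = 0.0021), which argues against level as the whole cause. Without mobile element and tRNA genes it was also larger (0.385 against 0.194, p = 0.0001, the smallest these permutations can give), which argues against reads shared between copies. A difference in chromosome structure or gene dosage between the strains may be involved, and was not tested.

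The third pattern is the rise of pyrE with both factors, by 3.45 ± 0.10 with aCcr2 and 1.20 ± 0.11 with aCcr3. The control also carried a plasmid. A plasmid copy of the REY15A pyrE and pyrF genes could raise pyrE only if absent from the control or less expressed there. Reads at pyrF were 0.0584% of those at pyrE with aCcr2 (2 against 3423), which argues against such a copy. In the control and aCcr3 libraries pyrF had 0 counts and pyrE had 384 and 844. Whether the chromosomal pyrE and pyrF genes are intact in this host was not tested. The rise of pyrE can therefore not be read as a response of nucleotide synthesis. A marker copy from another strain and a change in transcription stay open and untested.

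Other splits of the 6 libraries of a comparison into 3 and 3 were counted with edgeR. In each comparison 1 of 10 splits, the real one, gave as many called genes, and 10 splits are too few for a share under 0.05. The real splits called 1963, 1451 and 1756 genes, and the highest of the others was 0 each time, with 19, 56 and 127 genes at an unadjusted p under 0.05. Each other split puts libraries of both strains on each side, which adds the strain difference to the spread. Few calls in them were thus all but fixed in advance, and no conclusion is drawn from these counts.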
